A study of Homo sapiens with 18 samples.

How the data were processed

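Chromatin of KG-1 cells, a human myeloid leukaemia line, was immunoprecipitated with antibodies to the DNA topoisomerases TOP2A and TOP2B and sequenced as 50 bp paired-end reads, per the labels' protocols. Cells were crosslinked with 1% formaldehyde for 10 min, and 5 µg of TOP2A or 4 µg of TOP2B antibody was used. Of the 18 samples, 12 immunoprecipitated libraries were analysed and the 6 input samples were not analysed here. The etoposide experiment holds 8 libraries, 2 for each antibody with the vehicle and 2 with 100 µM etoposide for 1 h. The mitoxantrone experiment holds 4 libraries, 1 for each antibody without drug and 1 with 0.5 µM mitoxantrone for 1 h. Nothing in the labels says that the replicates came from separate cultures. P-values for peak numbers and bins therefore measure only the spread between these samples, which may be technical. P-values for overlaps come from shifted peak positions and hold no spread between samples.

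The submitters' processing notes name Bowtie2 2.2.5, bedtools 2.26.0, MACS 1.4 and the build hg19. For each library the authors deposited a MACS list, whose score per peak is the authors' own value and starts at 50, and a list of SISSRs sites. The deposited SISSRs lists hold a count of tags, a fold over background and a p-value per site, as judged from the values, because these lists have no header. The authors called each library separately, so replicates could be compared by overlap. Caller settings and the use of input are not given in the sources used here. The score of a peak was used only to rank or filter peaks within its own list. Read totals are not given in the sources used here. The tags in SISSRs sites summed to between 98275 and 48485872 per library, which moves with how many sites were called and is not the depth.

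Chromosomes 1 to 22 and X were used for overlaps and bins. Overlap was the share of the shorter MACS list with at least 1 bp in a peak of the other list. Chance came from 100 circular shifts of that list within each chromosome, with a one-sided p whose smallest value is 0.0099. Agreement of the callers used 20 shifts, with a smallest p of 0.0476. Chromosome length was taken as the largest peak end in any list. Reproducible regions were merged peaks that overlapped between both replicates of a group. A vehicle region was kept if it overlapped a reproducible etoposide region, and lost if no peak of either etoposide library overlapped it. Peak numbers were compared with a two-sided exact permutation test of log2 values, for which 2 against 2 libraries give a smallest p of 0.333.

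Peaks were counted by their midpoint in bins of 1 Mb, as log2 of peaks per 10000 peaks of the list with a pseudocount of 0.5 peaks. Bins with a mean of at least 5 peaks were tested with limma 3.58.1 (trend and robust) in R 4.3.3, at a Benjamini-Hochberg adjusted p of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap step was tested on simulated lists of 214612 peaks modelled on the TOP2A vehicle replicates, and recovered an excess over chance of 4.88% of peaks where overlaps had been planted for 5% of peaks. These lists were made by the same circular shifts, so the choice of chance was not tested. The bin test was tested on simulated data for TOP2A over 2887 bins, where it called 34% of 100 bins changed 2-fold, 4% of 100 bins changed 1.5-fold and none of the unchanged ones. For TOP2B over 2883 bins it called 58% and 5%, and 0.112% of the unchanged bins. The spread of the simulated counts was set in advance and not estimated from these libraries.

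The tests, their alternatives and the rule for named regions were fixed before the data were examined. The alternatives were a MACS score of at least 100, SISSRs sites widened to 200 bp, a reciprocal overlap of at least 50%, lists of equal length, shifts of 50 to 500 kb, bases covered, each replicate left out, the replicate number as a block, and for bins a size of 500 kb, a pseudocount of 2 peaks, no filter and 1 fit of all 8 libraries. The rule named, per antibody and experiment, the 3 kept, 3 lost and 3 gained regions with the highest value of their lowest score percentile within the lists concerned. It also named the 3 bins with the largest change in each direction among those past the threshold. The gene reference at hand is on GRCh38.p14 while the lists are on hg19, so no gene was assigned to any region, and the planned tests of promoters and of gene lists were not run.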

Results

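TOP2A and TOP2B occupancy was mapped in KG-1 cells with and without the topoisomerase II poisons etoposide and mitoxantrone, which hold the enzymes on cleaved DNA. The question was where each enzyme lies and how a 1 h exposure changes this. MACS peaks numbered 217253 and 249290 in the TOP2A vehicle libraries (replicates 1 and 2) and 36528 and 195016 with etoposide. For TOP2B they numbered 116111 and 297394 with the vehicle and 70459 and 103633 with etoposide. The mitoxantrone experiment, with 1 library per group, gave 109739 TOP2A peaks without drug and 7607 with mitoxantrone, and 9290 and 702 TOP2B peaks.

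**Figure D1:**
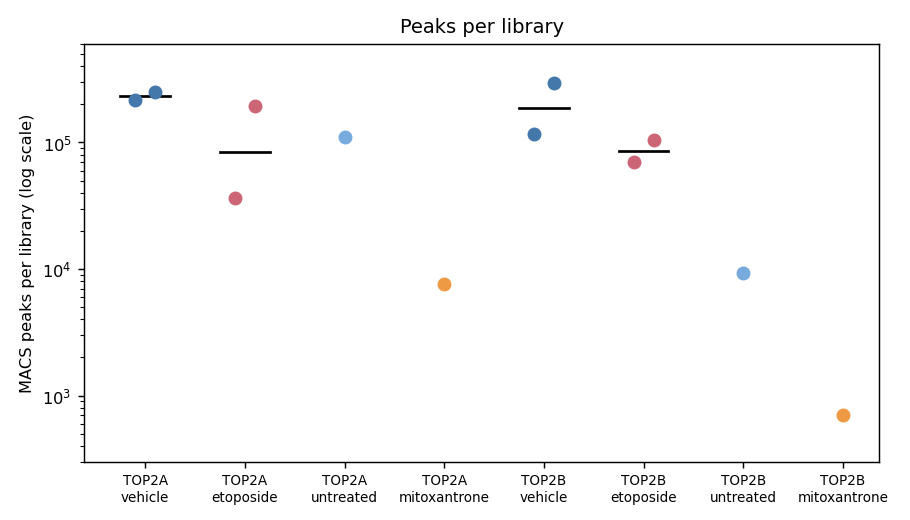
MACS peaks per library on a log axis; each point is 1 library and each bar the geometric mean of 2 replicates. The TOP2B mitoxantrone library has 702 peaks and the second TOP2B vehicle library 297394.

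Both TOP2A etoposide lists were shorter than both vehicle lists, with a geometric mean 2.76-fold lower (log2 ratio -1.46, SD of log2 values 0.14 with the vehicle and 1.71 with etoposide, n = 2 each). The ratio was 5.95-fold in replicate 1 and 1.28-fold in replicate 2. The TOP2B etoposide lists were 2.17-fold shorter (log2 ratio -1.12, SD 0.96 and 0.39, n = 2 each), with 1.65-fold in replicate 1 and 2.87-fold in replicate 2. The exact permutation p was 0.333 for both antibodies, the smallest that 2 against 2 libraries can give, so the test could not have passed 0.05 and decides nothing. Other measures gave other ratios. In SISSRs sites they were 3.31-fold and 1.27-fold (replicates 1 and 2) for TOP2A and 1.05-fold and 2.77-fold for TOP2B, and at a score of at least 100 they were 8.14-fold and 1.26-fold, and 3.72-fold and 2.87-fold. In bases covered they were 6.25-fold and 1.35-fold, and 1.78-fold and 3.72-fold. By that measure the TOP2A lists were not separate, with 28.3 Mb in etoposide replicate 2 and 26.1 Mb in vehicle replicate 1 (exact permutation p = 0.667). The mitoxantrone lists were 14.4-fold shorter for TOP2A and 13.2-fold shorter for TOP2B, with no replicate check. The size varied with the measure, from 12.01-fold in bases covered to 28.9-fold in SISSRs sites and 168-fold at a score of at least 100 for TOP2A. For TOP2B it was 4.42-fold, 7.91-fold and 12.5-fold. Tags in SISSRs sites also differed, with 48485872 and 12807542 in the TOP2A vehicle libraries and 3478285 and 16290087 with etoposide.

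The form of the peaks differed between the experiments. In the 8 libraries of the etoposide experiment 57.7% to 80.9% of peaks had exactly the smallest width of their list, 98 to 128 bp. In the mitoxantrone experiment the median width was 462 to 1126.5 bp, and at most 0.142% of peaks had the smallest width. SISSRs sites lay in 95.3% to 99.7% of MACS peaks of the etoposide experiment, and in 63.7% (TOP2A) and 32.7% (TOP2B) of peaks without drug and 23.8% and 12.8% with mitoxantrone. Each of these was above all 20 shifts (permutation p = 0.0476).

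Replicates of a group shared few peaks. TOP2A vehicle replicates overlapped in 2.92% of the shorter list against 2.38% by chance (1.22-fold), and TOP2A etoposide replicates in 2.19% against 1.75% (1.25-fold). TOP2B vehicle replicates overlapped in 3.44% against 2.81% (1.22-fold), and TOP2B etoposide replicates in 1.06% against 0.824% (1.29-fold). All 4 exceeded all 100 shifts (permutation p = 0.0099, the smallest they can give). The size of the excess depended on how chance was drawn. With local shifts the folds were lower, at 1.11 (TOP2A vehicle), 1.13 (TOP2A etoposide), 1.11 (TOP2B vehicle) and 1.18 (TOP2B etoposide). Each was still above chance (permutation p = 0.0099). With lists of equal length the TOP2A etoposide replicates fell to 0.947-fold (permutation p = 0.723).

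**Figure D2:**
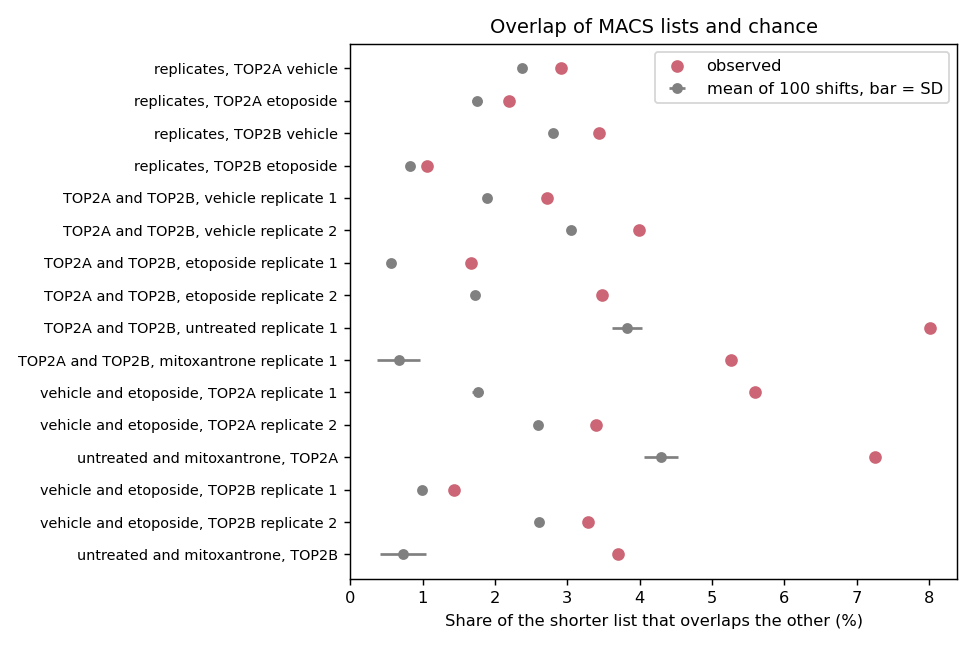
Share of the shorter MACS list that overlaps the other list, in percent; red points are observed values, grey points the mean of 100 shifts with its SD. Observed shares run from 1.06% to 8.01%.

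TOP2A and TOP2B peaks of the same treatment and replicate number overlapped more than by chance in all 6 pairs (permutation p = 0.0099 each). In the vehicle libraries the overlap was 1.44-fold chance in replicate 1 and 1.31-fold in replicate 2, and with etoposide 2.94-fold and 2.02-fold. Without drug in the mitoxantrone experiment 8.01% of TOP2B peaks overlapped a TOP2A peak (2.09-fold), and with mitoxantrone 5.27% did (7.87-fold). Under the alternatives all stayed above chance, but the folds ranged from 1.22 to 11.8 and from 1.19 to 3.28 with the vehicle (replicates 1 and 2), from 2.13 to 448 and from 1.70 to 16.9 with etoposide, from 1.85 to 11.6 without drug and from 5.47 to 200 with mitoxantrone. The highest came from wide peaks, a setting chosen after seeing the data, in the first 4, and from a score of at least 100, with 133 and 11 peaks, in the last 2. Only libraries of 1 replicate number were paired, and in the etoposide experiment these also shared exact peak starts. The vehicle pairs shared 150 and 344 starts, against 8 and 25.45 by chance. The etoposide pairs shared 16 and 487, against 0.6 and 7.1. Without such peaks the folds were 1.38 and 1.26 with the vehicle and 2.86 and 1.76 with etoposide. The excess is therefore not shown to be shared occupancy. Whether these folds differ between treatments was not tested.

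Of 6241 reproducible TOP2A vehicle regions, 9 (0.144%) overlapped a reproducible etoposide region, against 1.11 by chance (permutation p = 0.0099), and 5828 (93.4%) had no peak in either etoposide library. Of 3938 TOP2B vehicle regions, 10 (0.254%) were kept, against 0.68 by chance (permutation p = 0.0099), and 3751 (95.3%) had none. A single segment of chromosome 6, which has 6 blocks, held 6 of the 9 and 6 of the 10 kept regions. Without it 3 TOP2A regions were kept against 1.11 by chance, no longer past 0.05 (permutation p = 0.129), and 4 TOP2B regions against 0.67 (permutation p = 0.0099); this setting was chosen after seeing the data. Gained regions, with no vehicle peak, numbered 682 of 782 for TOP2A and 677 of 740 for TOP2B. Within a replicate number, etoposide and vehicle lists overlapped 3.17-fold and 1.31-fold over chance for TOP2A and 1.44-fold and 1.26-fold for TOP2B. Across replicate numbers they overlapped 1.29-fold and 1.20-fold for TOP2A and 1.43-fold and 1.15-fold for TOP2B. The 3.17-fold value ranged from 1.57-fold at a score of at least 100 to 19.8-fold with wide peaks. It was 2.49-fold without peaks that share a start, of which these 2 lists had 455 against 3.1 by chance, 4.82-fold with equal-length lists and 5.66-fold with reciprocal overlap. The 1.44-fold value of TOP2B replicate 1 ranged from 1.13-fold at a score of at least 100 to 21.8-fold with wide peaks. With SISSRs sites this TOP2B value was 2.45-fold. Most reproducible regions, with the vehicle and with etoposide, are expected from chance overlap of the replicates. Vehicle replicates overlapped in 2.92% of peaks against 2.38% by chance (TOP2A) and 3.44% against 2.81% (TOP2B). With etoposide the overlap was 2.19% against 1.75% (TOP2A) and 1.06% against 0.824% (TOP2B). Given how little replicates share, a region without a peak is not shown to have lost the enzyme, nor a gained region to have acquired it. No chance value was computed for the lost and gained shares. Chance placement would also leave most regions without a peak, since few single-library vehicle peaks overlapped an etoposide peak by chance. With SISSRs sites 384 of 9600 TOP2A (4%) and 370 of 6566 TOP2B (5.64%) vehicle regions were kept. Chance gave 11.07 and 7.58 regions (permutation p = 0.0099 each). Of the kept SISSRs regions, 185 (TOP2A) and 174 (TOP2B) lay in only 10 bins of 1 Mb per antibody. With equal-length lists 6 of 143 (4.20%) and 3 of 491 (0.611%) vehicle regions were kept, so fewer regions were kept out of far fewer. With 1 replicate left out no region is reproducible, so single-library vehicle peaks were used. The share that overlapped an etoposide peak was 0.933% in replicate 1 (0.295% by chance) and 2.65% in replicate 2 (2.03% by chance) for TOP2A. For TOP2B it was 0.869% (0.609% by chance) and 1.14% (0.903% by chance).

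All positions are on hg19, and no gene was assigned. The 3 leading kept TOP2A regions lay on chromosome 6 at 24650947 to 24651346, 24653159 to 24653434 and 24654589 to 24654816, and the 3 leading TOP2B ones at 24650945 to 24651605, 24658659 to 24659008 and 24653185 to 24653427 of the same chromosome. The leading lost TOP2A regions were at chromosome 2, 69263125 to 69263354, chromosome 7, 82088318 to 82088570, and chromosome 8, 62621564 to 62621754. The leading lost TOP2B regions were at chromosome 9, 16354618 to 16354782, chromosome 7, 44787207 to 44787345, and chromosome 1, 238407765 to 238407901. Gained TOP2A regions were led by chromosome 19, 20008051 to 20008212, chromosome 15, 22309284 to 22309454, and chromosome 4, 36227888 to 36228013. Gained TOP2B regions were led by chromosome 2, 101826154 to 101826276, chromosome 12, 70889972 to 70890173, and chromosome 13, 49812776 to 49812937. These lost and gained regions each had a peak in 2 or 3 of the 12 libraries, and chance overlap of 2 replicates can give such regions.

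The chromosome 6 regions belong to a segment from 24650945 to 24667129, which holds 6 separate blocks covering 2122 of its 16185 bp. All 6 blocks had a peak in each of the 8 libraries of the etoposide experiment, and no other region had a peak in all 8. By chance no region had a peak in all 8. In the mitoxantrone experiment 1 block had a TOP2A peak and 4 a TOP2B peak without drug, and 4 and 2 did with mitoxantrone.

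**Figure D3:**
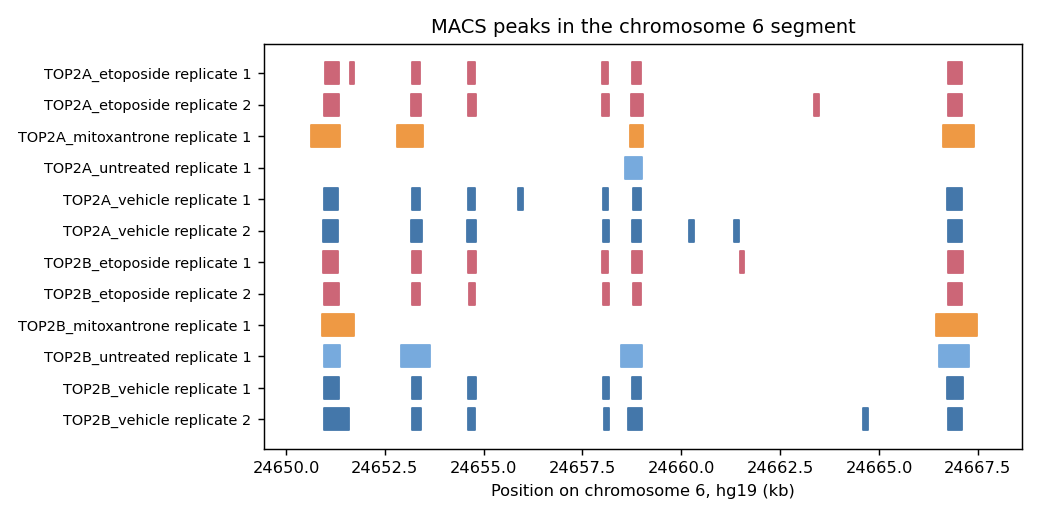
MACS peaks along chromosome 6 (hg19, kb) in 12 libraries, with each bar 1 peak, coloured by treatment. The 6 blocks recur in all 8 libraries of the etoposide experiment, with 7 peaks of those libraries between them.

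In the mitoxantrone experiment 7.25% of TOP2A mitoxantrone peaks overlapped a peak of the untreated library (1.69-fold chance, permutation p = 0.0099) and 3.70% of TOP2B peaks did (5.08-fold, p = 0.0099). In the other direction 0.507% of untreated TOP2A and 0.292% of untreated TOP2B peaks overlapped a mitoxantrone peak. Under the alternatives the TOP2B fold ranged widely. It was below chance with SISSRs sites, at 0.385-fold (permutation p = 0.97), and 20-fold with equal-length lists (permutation p = 0.0099). The kept TOP2A regions were led by chromosome 6, 24658575 to 24659025, chromosome 12, 126073473 to 126074106, and chromosome 14, 72140936 to 72141704. The kept TOP2B regions were led by chromosome 6, 24650918 to 24651716 and 24666446 to 24667471, and chromosome 14, 72140878 to 72141845. Lost TOP2A regions were led by chromosome 6, 139673187 to 139673431, chromosome 1, 226605398 to 226605646, and chromosome 3, 85123536 to 85123729. Lost TOP2B regions were led by chromosome 6, 24658473 to 24658997 and 24652908 to 24653641, and chromosome 22, 18717574 to 18718331. The chromosome 6 ones are blocks of the segment above, with peaks in 11 and 10 of the 12 libraries. Each of these lost TOP2B regions had a peak in the TOP2A mitoxantrone library. Lost here means only absent from the TOP2B mitoxantrone list of 702 peaks. The 7034 gained TOP2A regions were led by 3 blocks of the chromosome 6 segment, 24650642 to 24651371, 24666626 to 24667407 and 24652814 to 24653467, which had peaks in 10 or 11 of the 12 libraries. The 676 gained TOP2B regions were led by 3 on chromosome 8, at 142830221 to 142835277, 66311118 to 66315125 and 115455706 to 115459638. They had peaks in 4, 5 and 3 of the 12 libraries, and each had a peak in a vehicle library. Gained here means only absent from the TOP2B untreated list.

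Lists of the 2 experiments overlapped 1.13-fold to 1.37-fold over chance, and 5 of 8 pairs reached the smallest p. The vehicle and untreated lists were all among these, at 1.13-fold and 1.17-fold for TOP2A and 1.37-fold and 1.29-fold for TOP2B. In 3 of these 4 a setting chosen after seeing the data ended the call. Equal-length lists gave 1.21-fold (permutation p = 0.248) and 1.05-fold (permutation p = 0.436) for TOP2B vehicle 1 and 2, and reciprocal overlap gave 0.972-fold (permutation p = 0.614) for TOP2A vehicle 1. In the other settings both TOP2B vehicle lists stayed past 0.05. Their folds ran from 1.23 with local shifts to 2.58 at a score of at least 100 for vehicle 1, and from 1.15 to 1.86 for vehicle 2. Of the etoposide and mitoxantrone lists, TOP2A replicate 1 (1.14-fold, permutation p = 0.139) and TOP2B replicate 1 (1.31-fold, p = 0.0594) did not pass 0.05, TOP2A replicate 2 did (1.20-fold, p = 0.0099) and TOP2B replicate 2 did (1.35-fold, p = 0.0297). Other settings moved 3 of these 4 across 0.05 in either direction, and TOP2B replicate 1 to 0-fold with reciprocal overlap. The drugs differ in dose, 100 µM and 0.5 µM, and in experiment.

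Peak density along the chromosomes was compared in bins, without regard to replicate number. With limma, 0 of 2887 bins of 1 Mb were called for TOP2A, with 98 at an unadjusted p under 0.05, and 0 of 2885 for TOP2B, with 134. No bin was therefore named by the rule, which followed this fit. With the replicate number as a block, 3 TOP2A bins, all of higher density with etoposide, and 0 TOP2B bins were called. The median absolute log2 change was 0.18 for TOP2A and 0.17 for TOP2B. Leaving out TOP2A etoposide replicate 2 gave 620 calls, and leaving out TOP2B etoposide replicate 2 gave 134. These fits set 1 etoposide library against 2 vehicle libraries, so the spread comes from the vehicle libraries alone, the lone library is assumed to vary like them, and the counts describe that library. A 2-fold change could often be missed, as only 34% (TOP2A) and 58% (TOP2B) of such bins were called in simulated data. The spread in those data was a set value, so the shares are only a rough guide to these libraries.

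Across bins, densities of the 2 vehicle replicates correlated at 0.868 (TOP2A) and 0.840 (TOP2B), and of the 2 etoposide replicates at 0.672 and 0.690. Vehicle and etoposide correlated at 0.668 and 0.672 in replicate 1 and at 0.881 and 0.835 in replicate 2. Bins are not replicates, so no p is given. In all 8 libraries of the etoposide experiment chromosome 8 held 1.96 to 2.08 times the mean density per bin and chromosome 5 held 0.79 to 0.818 times. From 90 to 160 Mb of chromosome 5 the density was 0.501 to 0.536 times the mean, and from 50 to 140 Mb of chromosome 8 it was 2.28 to 2.46 times. These windows were chosen after their values were seen. In the mitoxantrone experiment the same windows held 0.0588 to 0.342 and 1.39 to 5.94 times the mean. The 0.0588 and the 5.94 came from the TOP2B mitoxantrone library of 702 peaks. There 1 peak in a bin already equals 4.11 times the mean, so these 2 values are coarse.

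**Figure D4:**
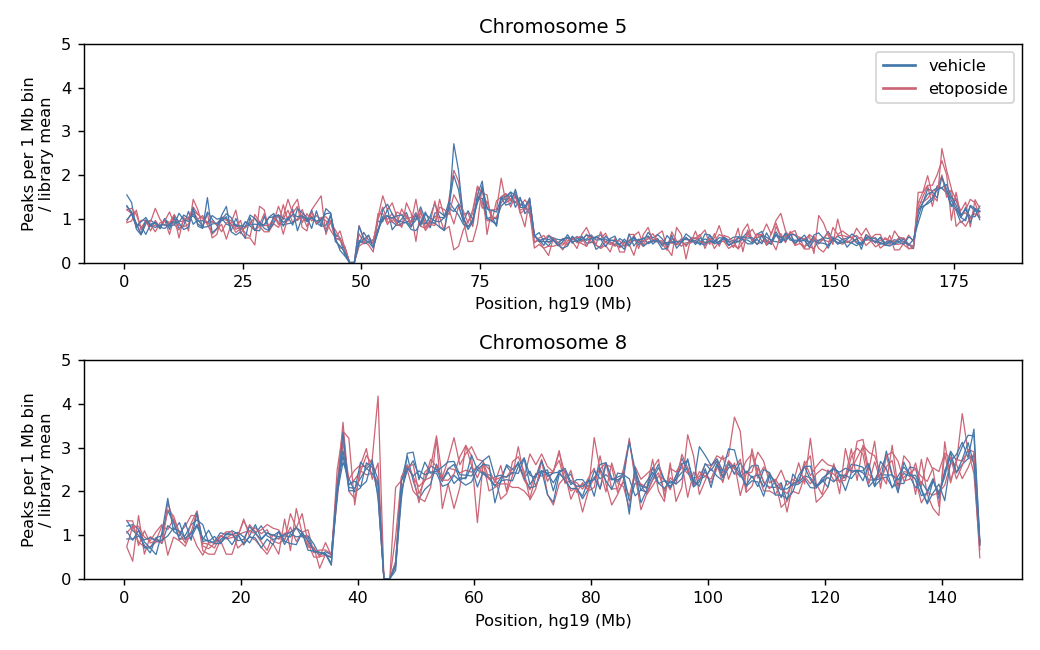
Peaks per 1 Mb bin divided by the library mean along chromosomes 5 and 8 (hg19, Mb) for the 4 vehicle and 4 etoposide libraries, 1 line each. Density lies near 0.5 from 90 to 160 Mb of chromosome 5 and above 2 over much of chromosome 8.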

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

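Of 272 alternative values, 247 kept their direction and side of the threshold or, with no usable test, moved by less than the SD between replicates (counts, by less than 1.5 times; without replicates, within the 95% binomial interval), among them all 42 for TOP2A with TOP2B, whose folds ranged up to 448, and 21 of 22 for kept vehicle regions, whose shares ranged widely. The settings for lists between experiments, wide peaks, shared starts and the chromosome 6 segment were chosen after seeing the data. Leaving out 1 replicate gave etoposide log2 ratios of peak number of -2.57 to -0.354 (TOP2A) and -1.52 to -0.721 (TOP2B), within the wide SD pooled over both groups, which shows no stability. The cause of each change below was not tested. Without the chromosome 6 segment 0.0481% of TOP2A vehicle regions were kept, no longer past 0.05. As a replicate block the vehicle peaks that overlapped were 1.79% (TOP2A, 1.54-fold chance) and 1.00% (TOP2B). Equal-length lists turned TOP2A etoposide replicates to 0.947-fold, and SISSRs sites turned TOP2B untreated against mitoxantrone to 0.385-fold. Between experiments, reciprocal overlap gave 0.972-fold (TOP2A vehicle 1), 11.5-fold (TOP2A etoposide 1), 1.42-fold (TOP2A etoposide 2, no longer past 0.05) and 0-fold (TOP2B etoposide 1). A score of at least 100 gave 7-fold and 1.17-fold for TOP2A etoposide 1 and 2. Equal-length lists gave 1.73-fold (TOP2A etoposide 1, now past 0.05), 1.21-fold and 1.05-fold (TOP2B vehicle 1 and 2) and 3.13-fold (TOP2B etoposide 2), the last 3 no longer past it. TOP2B etoposide 2 also gave 0.569-fold with SISSRs sites, 1.15-fold with local shifts and 2.02-fold with wide peaks. For mitoxantrone the log2 ratio of peak numbers was -7.40 (score), -4.85 (SISSRs) and -3.59 (bases) for TOP2A, and -2.98 (SISSRs) and -2.14 (bases) for TOP2B. Leaving out 1 library gave 0 to 620 bins for TOP2A and 0 to 134 for TOP2B. With the replicate number as a block, 3 TOP2A bins were called and 0 TOP2B bins. The log2 ratios of peak number, -1.46 and -1.12, cannot change with a block, so their place among the 247 shows nothing. The exact permutation p within replicate numbers was 0.5 for both. The labels number the replicates but do not say what libraries of 1 number share. Deviations correlated at 0.00276 (TOP2A) and -0.139 (TOP2B) across bins. Yet the 12 pairs of 1 number in the etoposide experiment shared 2263 exact peak starts, against 111.15 by chance. A link by replicate number is therefore not excluded. Chance was 0 in 2 alternatives of list overlap, which give no fold, and in 2 of kept regions, given as shares. Promoter and gene list alternatives were not run.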

Other observations

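All tests of explanations here were chosen after the patterns were seen. Regions kept under etoposide in the SISSRs lists gathered in few places, with 185 of 384 for TOP2A and 174 of 370 for TOP2B in 10 bins of 1 Mb each. The bin from 49000001 to 50000000 of chromosome 4 held 32 of the TOP2A and 31 of the TOP2B regions. The bin from 42000001 to 43000000 of chromosome 10 held 26 and 29, and the bin from 86000001 to 87000000 of chromosome 8 held 29 and 19. Whether reads map uniquely in these bins was not examined. The kept SISSRs regions are therefore not shown to be retained occupancy.

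Libraries of 1 replicate number in the etoposide experiment shared exact peak starts. All 12 such pairs shared more starts than any of 20 shifts, 2263 in all against 111.15 by chance, while 6 of 16 pairs with other numbers did, 217 against 130.

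The 6 blocks of the chromosome 6 segment were chosen for a peak in all 8 libraries of the etoposide experiment, so those libraries cannot test them. The 2 untreated libraries of the other experiment took no part in the choice. They had peaks on 5 of 12 possible blocks, against 0.25 by chance (permutation p = 0.0099), which argues against an effect of etoposide as the source of these peaks. Extra copies of the whole segment would place peaks along its length, but in the 4 libraries of the mitoxantrone experiment 11 of 11 peaks lay on the blocks, against 3.87 after shifts within the segment (permutation p = 0.0099). This argues against such copies as the only source of the blocks. Some extra copies beside another source are not excluded, as peak density between the blocks was 1.13 times the mean in the etoposide experiment (95% Poisson interval 0.454 to 2.33). DNA from another source than the chromosome may be the cause, with a peak on 1 or more blocks in 4 of 4 libraries of the mitoxantrone experiment. That and binding by both enzymes cannot be told apart, because the input libraries were not analysed here.

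Narrow peaks that replicates hardly share may be piles of duplicate fragments called as peaks. Peaks of the smallest width overlapped between replicates 1.02-fold to 1.24-fold over chance, while peaks wider than 2 times the narrowest, a far shorter list, did so 3.09-fold to 20.1-fold. The shares themselves were higher for narrow peaks in the vehicle groups, 1.63% against 1.38% for TOP2A and 2.41% against 1.39% for TOP2B, and lower with etoposide, 1.19% against 1.96% and 0.702% against 1.35%. Drawn at random to the number of wide peaks, narrow peaks overlapped 1.03-fold to 1.21-fold over chance, under the lower 95% Poisson bound of wide peaks in 4 of 4 groups. With etoposide the wide folds rest on 18 (TOP2A) and 30 (TOP2B) overlapping peaks, and the bound leaves out the spread of chance. Any narrow calls that replicate poorly would give this result, so it does not single out duplicate fragments. An effect of etoposide is argued against, as the highest share of smallest-width peaks in a vehicle library was 80.9%, above every etoposide library. Read duplicates themselves were not analysed here.

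The density steps on chromosomes 5 and 8 were also in the vehicle libraries, whose highest density from 90 to 160 Mb of chromosome 5 was 0.522 times the mean, which argues against an effect of etoposide. A candidate explanation is the number of copies of these segments in the cells, with at most 0.536 times the mean in any of the 8 libraries. Copy number and regional occupancy cannot be told apart, because the input libraries were not analysed here.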
